A study of Homo sapiens with 4 samples.

How the data were processed

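Chromatin immunoprecipitation with an antibody to BRCA2 was followed by high-throughput sequencing in hTert-HME1 cells, a human mammary epithelial line made immortal with telomerase. Per the labels' protocols, cells in log-phase growth were crosslinked with formaldehyde, nuclei were sonicated, and libraries were made from the precipitated DNA and from input chromatin. There were 2 BRCA2 ChIP libraries and 2 input libraries. The labels do not say whether the replicates came from separate cultures, so the authors' FDR measures only the spread between these libraries, which may be technical.

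The submitters' processing notes name cutadapt 1.8.1, Bowtie 1.1.1, SAMtools, Picard 1.92, MACS2 and DiffBind, and the hg19 genome build, with no order or settings. The series' design text states that the ChIP replicates were compared with the input replicates by DiffBind. The model used inside DiffBind, its scaling and the release of the gene annotation are not given in the sources used here. The authors' deposited table gives, for each site, a mean log2 concentration of normalized reads in the ChIP group and in the input group, per the file headers. Its log2 fold is the ChIP concentration minus the input concentration, and the authors' fold and that difference lay within 0.01 of each other at every site. The FDR (a q-value) of each site is also the authors' deposited value, and the table holds sites up to an FDR of 0.05. Each site is paired with its nearest gene start, with overlapping genes and with some genes that end nearby, so that the 15131 sites fill 23317 rows. For example, a site 2430 bp from the start of KRT16 is also paired with JUP. It lies 612 bp past the end of JUP and 168602 bp from its start. A second deposited list of gene symbols holds no measurement and was not used.

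The authors' table holds group means and no value per library. The depth of each library is therefore unknown here, no spread between replicates could be computed, and no test of ChIP against input was run beyond the authors' own. The design written before the data were examined provided for this case: the authors' FDR was counted as deposited. Because unadjusted p-values are not used here, a count adjusted over the list alone could not be computed for the gene lists. Start positions in the table count from 0, as the distances of 100% of the upstream rows on the forward strand show, and are given here counted from 1.

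A site was placed in 1 class, in the order over a gene start, over a gene end, inside a gene, and outside genes. Sites over a listed gene start, or within 1 kb of one by the listed distance, were called promoter sites. That distance runs to a fixed edge of the site, so a site whose other edge is nearer can be left out. At ZNF219, for example, the listed distance was 1052 bp and the shortest 553 bp. The listed start is the outermost one of a gene, so alternative starts inside a gene count as inside. Gene rows were matched by Entrez ID, then by symbol, to a table of 20056 protein-coding genes of assembly GRCh38.p14, which was used for names, lengths and genes per chromosome and for no coordinate. Of the 23317 rows, 13849 matched a protein-coding gene and 5806 matched no gene. In 35 rows with 18 symbols, the symbol had been turned into a date. Those genes entered the tests by Entrez ID and are not named. A gene counted as having a site when any site was paired with it, whatever the distance. The fold given for a list member is that of its strongest site, which may lie past its end or far from its start.

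The 20 gene lists and 5 families of coding genes were fixed before the data were examined. They were homologous recombination and Fanconi anemia, other DNA repair, DNA replication, mitosis, histones, ribosomal proteins, the spliceosome, oxidative phosphorylation, Pol II pausing, heat shock, immediate early genes, EGF receptor signalling, interferon-stimulated genes and fragile site genes, with markers of basal, luminal, fibroblast, immune, and neuronal or liver cells. 1 more list and some genes that the naming rule takes are not reported here. The families were ZNF genes, olfactory receptors, protocadherins, keratins and HOX genes. Each was compared with the other protein-coding genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over all 25. Each was also set against 10000 random lists matched on gene length in 20 bins. Genes are not replicates, and neighbouring genes can share a site.

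Shares carry 95% Wilson intervals, which cover counting error only. Medians were compared by two-sided permutation tests with 100000 resamples. Sites per chromosome were compared with the number of protein-coding genes by exact binomial tests with Benjamini-Hochberg adjustment over 23 chromosomes. A single step in the input level along each chromosome was sought by least squares, with 10000 permutations of the site order. The named genes were set by rule: the 10 sites with the largest log2 fold that carry a symbol, the 10 with the smallest FDR, the 5 genes with the most sites, and up to 4 members by largest fold from each list that passed and from the recombination, basal, luminal and immediate early lists. Other genes named below were chosen after their values were seen.

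The tests were tested on simulated data with known answers. With a planted share of 80% on the 20056 genes, the Fisher test called 100% of the planted lists. It also called 9.25% of the lists with no planted change, since gene length alone gives some lists more sites and others fewer. The length-matched draw called 99.0% of the planted lists and 0.75% of the others, and is given wherever it ends a call. In the simulation only gene length set the unplanted lists apart. The draw matches on gene length, so its low rate was fixed by design. Neighbouring genes that share a site were not simulated, so the rate for such families is unknown. The planted share of 80% was above that of most lists that passed, so power at lower shares was not tested. The median test called 100% of runs with a planted shift of 0.16. The chromosome test called 100% of runs with a planted ratio of 0.5 and 0.174% of unchanged chromosomes. Its simulated sites were independent and drawn in proportion to gene counts, as the test assumes, so a low rate was fixed by design. Sites that cluster along genes were not simulated. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Alternatives were a stricter FDR, a minimum fold, wider promoter windows, weighting by width, merged sites, and sites near starts only. Analyses of the sites past gene ends, of small RNA genes and of input steps were chosen after seeing the data.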

Results

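BRCA2 is a protein of homologous recombination. The series asked where it lies on chromatin in dividing mammary epithelial cells, by comparing 2 BRCA2 ChIP libraries with 2 input libraries. All folds, concentrations and FDR values below are the authors' own, from the authors' deposited table, and are means over a group with no value per library. Positions are on hg19. No control antibody was analysed here, so non-specific pull-down cannot be told apart from BRCA2 binding at the sites and gene lists below.

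The strongest BRCA2 sites lay at gene starts on many chromosomes. In the authors' deposited table, a site on chromosome 7 from 154794723 to 154795222, over the start of PAXIP1, a gene of the DNA damage response, had a log2 fold of 6.87 and an FDR of 4.61e-59. PRDM10, a zinc finger factor, had 6.61, and FLCN, the folliculin gene, and ANKRD13A each had 6.49. A site from 137673470 to 137673969 on chromosome 5, just inside CDC25C, a phosphatase of mitotic entry, had 6.38 and the highest ChIP concentration of the table, 12.14 on the log2 scale. CCDC85C had 6.27, PRKCI, an atypical protein kinase C, 6.23, and HYAL2, a hyaluronidase, 6.21.

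The largest fold of the authors' deposited table was 7.96, at a site 181 bp upstream of SLC35E2B on chromosome 1. SLC35E2 had 6.44. These genes are near-identical copies, with low input concentrations of 3.45 and 3.52, and how reads were divided between them is uncertain. PAXIP1 and CCDC85C had even lower input, 2.99 and 2.40, so their large folds rest on few input reads.

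The sites with the smallest FDR in the authors' deposited table were those of MGEA5, the O-GlcNAcase gene, at 4.07e-227 with a log2 fold of 5.74, and PRKCI at 6.18e-218. BCCIP, whose product binds BRCA2, had a log2 fold of 5.60 and an FDR of 8e-204 at a site over its start, from 127511731 to 127512230 on chromosome 10. ULK4 had a log2 fold of 5.64, TAF15 5.75, EIF3B 6.13, PMVK 5.84, ZNF300 5.71 and STK35 5.86. Of the 10 sites with the largest fold, 9 lay within 1 kb of a gene start, as did 10 of the 10 with the smallest FDR. ANKRD13A and PRKCI were in both lists.

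The table held 15131 sites, of which 15129 were above input and 2 below. The median log2 fold above input was 1.15, with quartiles of 0.93 and 1.5, which is a 2.22-fold enrichment. A log2 fold of at least 2 was reached by 1652 sites (10.9%) and of at least 4 by 307 (2.03%). The sites below input lay inside ZNF705G on chromosome 8, at a log2 fold of -0.82 and an FDR of 0.0449, and near AC018696.7 on chromosome 2, at -0.77 and 0.0474. Both were chosen after their values were seen. At an FDR under 0.001 the number above input was 6741.

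KCNMA1, a potassium channel gene on chromosome 10, had the most sites of any protein-coding gene, 16, none of them within 1 kb of its start. Their median log2 fold was 0.985 and the largest 1.85. EIF2B5 was paired with 13 sites, and OPA3, PTPRE and ZMIZ1 with 11 each, with largest folds of 1.94, 2.95, 1.97 and 1.78. PTPRE and ZMIZ1 also lie on chromosome 10, where the input level was high.

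Promoter sites carried larger folds than other sites. Within 1 kb of a gene start lay 5042 sites, 33.3% of all (95% Wilson interval 32.6 to 34.1). Their median log2 fold was 1.26, against 1.10 at the 10089 other sites. The difference of 0.16 had a permutation p of 1e-05, the smallest that the resamples can give. PAXIP1, FLCN and PRKCI were among the 234 of 307 sites with a log2 fold of at least 4 that lay at promoters, 76.2% (71.2 to 80.6). Under a log2 fold of 1 the promoter share was 25.2% (24.0 to 26.5). The odds of a promoter position were 6.68 times higher at a log2 fold of at least 4 than below it (two-sided Fisher exact p = 2.01e-54). A window of 3 kb or 5 kb raised the promoter share to 42.05% or 48.15%.

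**Figure D1:**
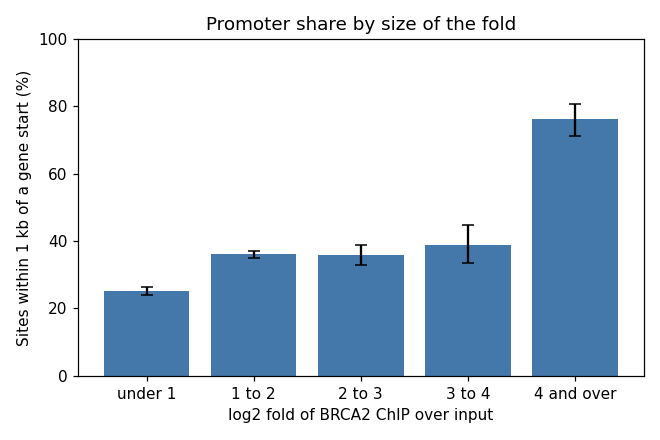
Share of sites within 1 kb of a gene start (vertical axis, percent) in bins of log2 fold (horizontal axis), with 95% Wilson intervals as error bars. The share was 25.2% under a log2 fold of 1, between 35.8% and 38.9% from 1 to 4, and 76.2% at 4 and over.

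By class, sites inside a gene were the most frequent, with 7138 sites (47.2%, interval 46.4 to 48.0). Sites over a gene start numbered 3338 (22.1%), those upstream of the nearest gene 2873 (18.99%), those downstream 1640 (10.8%), and those over a gene end 142 (0.94%). Median log2 folds were 1.24 over starts, 1.14 inside genes, 1.28 over ends, 1.10 upstream and 1.11 downstream. The share of the genome in each class was not used here, so these shares carry no expected value.

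Genes of homologous recombination and the Fanconi anemia pathway, in which BRCA2 itself acts, had sites more often than other genes. Of 63 members, 46 (73.0%) had a site, against 44.2% of other protein-coding genes (odds ratio 3.41, adjusted Fisher exact p = 1.83e-05). The excess was not particular to this list. Odds ratios were larger for some others, such as spliceosome (3.71) and ribosomal protein genes (5.87), and smaller for others, such as DNA replication genes (2.89). The largest fold of this list in the authors' deposited table was that of UIMC1, which binds ubiquitin in the BRCA1-A complex. It was 5.42, at a site inside the gene and 16023 bp from its start. FANCI had 3.90 over its start, ATRIP 3.64 over its end, and RAD51B 3.24 deep inside the gene. A site within 1 kb of the start was held by 39 of the 63. At an FDR under 0.01, 35 of the 63 had a site (adjusted exact p = 0.00662), where length-matched lists had a median of 26, and the call was lost against those lists (length-matched adjusted p = 0.0532). Other DNA repair genes had sites at 35 of 56 (62.5%, adjusted exact p = 0.0122). ERCC1 had 5.48 at a site 582 bp past its end, PRKDC 5.34, PMS1 2.84 and OGG1 2.52. Against lists matched on gene length the adjusted p for other DNA repair was 0.0714. Near starts, 32 of the 56 had a site (adjusted exact p = 2.04e-07), and the length-matched adjusted p was 0.000455. Other DNA repair did not pass at an FDR under 0.01 (28 of 56, adjusted exact p = 0.0820), at a log2 fold of at least 1 (27 of 56, adjusted exact p = 0.0751), or without chromosomes 4, 10, 13, 14, 18 and X, an alternative chosen after seeing the data (adjusted exact p = 0.0519).

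Among cell cycle and chromosome genes, replication and histone genes were high under each threshold on FDR or fold. DNA replication genes had sites at 39 of 56 (69.6%, adjusted exact p = 0.000576), led by MCM4 at 5.34, CDT1 at 4.48, CDC45 at 3.76 and TYMS at 3.66. MCM4 and PRKDC share 1 site within 1 kb of both starts, from 48873104 to 48873603 on chromosome 8. Mitosis and centrosome genes had sites at 29 of 48 (60.4%, adjusted exact p = 0.0400), among them CENPE, a kinetochore motor, at 5.19 and TPX2, a spindle factor, at 2.57. The length-matched adjusted p for mitosis genes was 0.149. Near starts, 22 of the 48 had a site (adjusted exact p = 0.00146, length-matched adjusted p = 0.00937). Mitosis genes did not pass at an FDR under 0.01 (24 of 48, adjusted exact p = 0.107), at a log2 fold of at least 1 (19 of 48, adjusted exact p = 0.648), or without the 6 chromosomes (adjusted exact p = 0.363). Replication-dependent histone genes, which are very short, had sites at 40 of 66 (60.6%, adjusted exact p = 0.0148), where length-matched lists had a median of 11. HIST1H4J had 3.09, HIST1H4H 2.46 at a site 11338 bp upstream, and HIST1H1E 2.20.

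Genes of basic cell functions were among the highest groups. Cytosolic ribosomal protein genes had sites at 65 of 79 (82.3%, odds ratio 5.87, adjusted exact p = 5.68e-11), with RPL22 at 5.14, RPL35 at 4.96 and RPL19 at 4.56. Spliceosome genes had sites at 50 of 67 (74.6%, adjusted exact p = 3.62e-06), with CDC40 at 4.07 and SF3A2 at 2.78. Oxidative phosphorylation genes had sites at 56 of 76 (73.7%, adjusted exact p = 1.91e-06), led by NDUFB1 at 5.27, UQCRC2 at 4.77 and UQCRH at 4.63. Genes of Pol II pausing and elongation had sites at 30 of 43 (69.8%, adjusted exact p = 0.00232), with AFF1 at 5.27, HEXIM1, an inhibitor of P-TEFb, at 4.37 and POLR2A at 4.08. Most of these genes had sites at their starts: 53 ribosomal protein, 45 spliceosome, 45 oxidative phosphorylation and 23 pausing genes had one within 1 kb. The named sites of RPL22 and AFF1 lay inside the genes, 9800 and 71785 bp from their starts, and that of SF3A2 817 bp past its end.

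Heat shock and unfolded protein response genes had sites at 26 of 38 (68.4%, adjusted exact p = 0.00637), with EIF2AK3 at 3.22 and ATF4 and HSPA5 at 2.81. EGF receptor and MAPK genes had sites at 25 of 40 (62.5%, adjusted exact p = 0.0390), with ARAF at 5.12, SHC1 at 4.59 and SPRY4 at 3.51. The length-matched adjusted p of the EGF receptor list was 0.142, and near starts, with 14 of 40, its adjusted exact p was 0.117. It passed the exact test at an FDR under 0.01 and at a log2 fold of at least 1 (22 of 40 in both, adjusted exact p = 0.0368 and 0.0207), but not against length-matched lists, with length-matched adjusted p of 0.128 and 0.0650.

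Immediate early genes, which growth factors and stress switch on within minutes, had sites at 31 of 43 (72.1%, odds ratio 3.26, adjusted exact p = 0.000761). FOS had a log2 fold of 6.07 over its start in the authors' deposited table, EGR1 had 5.27, FOSL1 5.03 and CYR61 4.08. The median of the strongest site per gene was 3.19 in this list and 1.31 over all 8886 genes with a site. Only 7 of the 43 had a site within 1 kb of the start (odds ratio 0.63, adjusted exact p = 0.417).

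Among cell type markers, the basal list was high and the luminal list was not. Basal and myoepithelial markers had sites at 31 of 37 (83.8%, odds ratio 6.51, adjusted exact p = 4.36e-06), including THBS1 at 3.83 and S100A2 at 3.77. KRT17 and KRT16, neighbouring keratins of similar sequence, share 1 site with 3.96, which lies 609 bp past the end of KRT17 and 2430 bp upstream of KRT16. Luminal markers had sites at 12 of 35 (34.3%, adjusted exact p = 0.334), led by AREG at 5.24, PRLR at 2.76, ERBB3 at 2.27 and ELF5 at 1.77. AREG has a near-identical copy, AREGB, so its value is uncertain. The difference between these 2 lists was not tested. Only 7 basal markers had a site within 1 kb of the start (odds ratio 0.76, adjusted exact p = 0.727). Fibroblast markers had sites at 12 of 27 (adjusted exact p = 1), immune markers at 9 of 31 (adjusted exact p = 0.130), and neuronal and liver genes at 10 of 32 (adjusted exact p = 0.178). Within 1 kb of the start, fibroblast markers (1 of 27, adjusted exact p = 0.0163) and immune markers (2 of 31, adjusted exact p = 0.0276) were below other genes.

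Some gene families were nearly without sites. Olfactory receptor genes had sites at 3 of 392 (0.77%, adjusted exact p = 1.95e-93), of which OR2K2 had the largest fold, 2.23, at a site 27971 bp from the gene. HOX genes had a site at 1 of 39, HOXB3 at 1.41 (adjusted exact p = 6.13e-08). Keratins had sites at 16 of 55 (29.1%, adjusted exact p = 0.0400, length-matched adjusted p = 0.311), with KRT5 at 2.99 and KRT14 at 2.71. Near starts, 2 of the 55 keratins had a site (adjusted exact p = 0.000165, length-matched adjusted p = 0.000455), and the list did not pass at an FDR under 0.01 (15 of 55, adjusted exact p = 0.207) or at a log2 fold of at least 1 (15 of 55, adjusted exact p = 0.339). Genes named ZNF had sites at 257 of 509 (50.5%, adjusted exact p = 0.00968, length-matched adjusted p = 0.149). ZNF630 had 5.79 at a site inside the gene, 50431 bp from its start, ZNF300 5.71, ZNF219 5.53 and ZNF335 4.82. Near starts, 185 of the 509 had a site (adjusted exact p = 2.52e-10, length-matched adjusted p = 0.000455). The excess of ZNF genes was lost at an FDR under 0.01 (194 of 509, odds ratio 1.04, adjusted exact p = 0.735) and at a log2 fold of at least 1 (182 of 509, odds ratio 1.04, adjusted exact p = 0.725), and without the 6 chromosomes the list did not pass (adjusted exact p = 0.0726). Protocadherins had sites at 23 of 66 (adjusted exact p = 0.163), but 15 of these genes share 1 weak site on chromosome 5, with a log2 fold of 0.76 and an FDR of 0.0481. They were below other genes near starts (1 of 66, adjusted exact p = 1.75e-06), at an FDR under 0.01 (7 of 66, adjusted exact p = 1.38e-05) and at a log2 fold of at least 1 (7 of 66, adjusted exact p = 6.55e-05). Fragile site genes (21 of 35, adjusted exact p = 0.115) and interferon-stimulated genes (22 of 43, adjusted exact p = 0.461) did not pass.

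**Figure D2:**
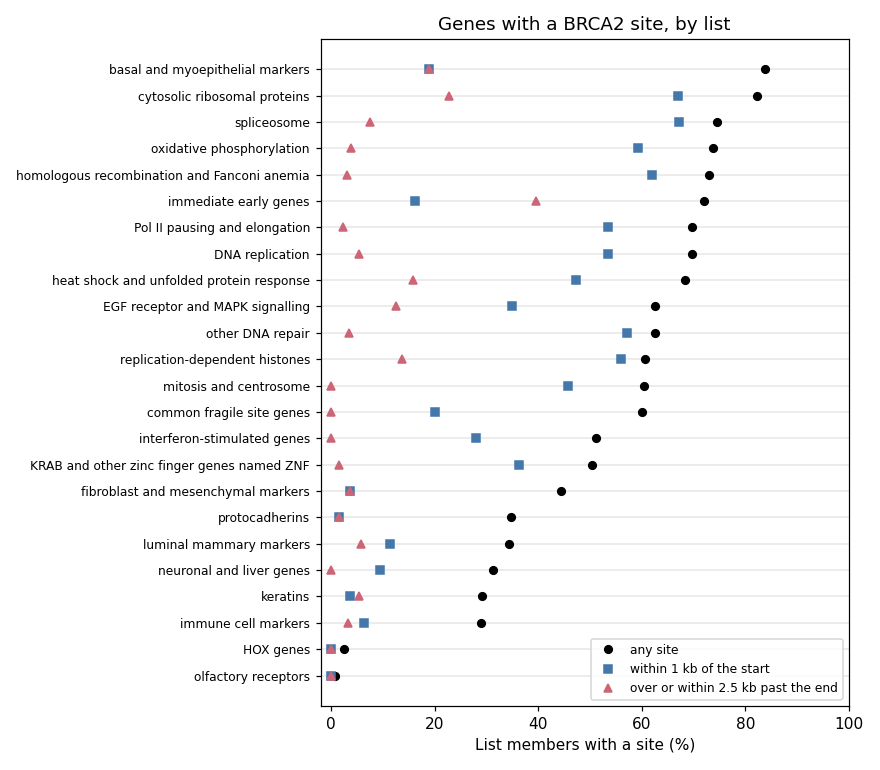
Share of members with a site (horizontal axis, percent) for 24 gene lists, counting any site (circles), sites within 1 kb of the start (squares), or sites over or within 2.5 kb past the end (triangles). Immediate early genes had 72.1%, 16.3% and 39.5%, and ribosomal protein genes 82.3%, 67.1% and 22.8%.

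Chromosome 4 held far fewer sites than its genes would give. It had 177 sites where its 770 protein-coding genes gave an expected 583 (ratio 0.30, adjusted exact binomial p = 1.46e-87), among them the strong sites of CENPE, AFF1 and AREG. The X chromosome had a ratio of 0.43 (adjusted exact p = 6.78e-61), chromosome 14 of 0.61, chromosome 19 of 0.77, chromosome 18 of 0.84 and chromosome 11 of 0.89. Chromosome 10, with KCNMA1, PTPRE and ZMIZ1, had the highest ratio, 1.58 (adjusted exact p = 1.48e-36), followed by chromosome 13 with 1.32 and chromosome 2 with 1.23. In all, 10 of 23 chromosomes were above and 6 below.

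The input concentration differed along with these counts on some chromosomes and not on others. The median input of the sites on chromosome 4 was 4.51, lower than the 5.42 of all sites above input by 0.91 on the log2 scale, or 0.532 of that level. On chromosome 10 it was higher by 0.49 and on chromosome 13 by 0.14. On chromosomes 14, X and 18, below in sites, the differences were -0.39, -0.31 and -0.25. Chromosomes 19 and 11, also below in sites, differed by -0.08 and 0.02, and chromosomes 2 and 3, above in sites, by 0.01 each. The others above in sites, chromosomes 1, 5, 8, 12, 15 and 20, differed by between -0.04 and 0.02. Sites with a log2 fold of at least 2 numbered 7.40 per 100 genes on chromosome 4 and 8.27 over all chromosomes, and weaker sites 15.6 and 67.5. With strong sites alone, an alternative chosen after seeing the data, 0 chromosomes passed the test in either direction. These are 1652 of the 15129 sites above input, so the test had less power for ratios near 1. For chromosomes with such ratios, the lost call does not show that the difference was gone.

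**Figure D3:**
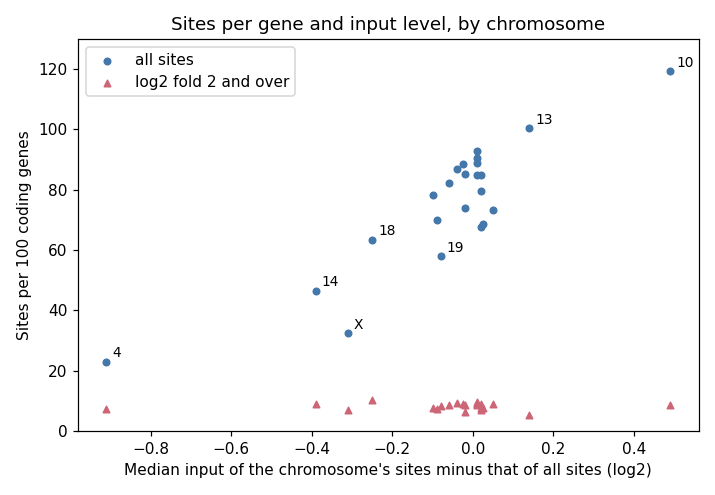
Sites per 100 protein-coding genes (vertical axis) against the median input of a chromosome's sites minus that of all sites (horizontal axis, log2), for all sites (circles) and those with a log2 fold of at least 2 (triangles), 1 point per chromosome. Chromosome 4 had 22.99 and chromosome 10 had 119.3 sites per 100 genes, and strong sites numbered 7.40 and 8.45.

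**Figure D4:**
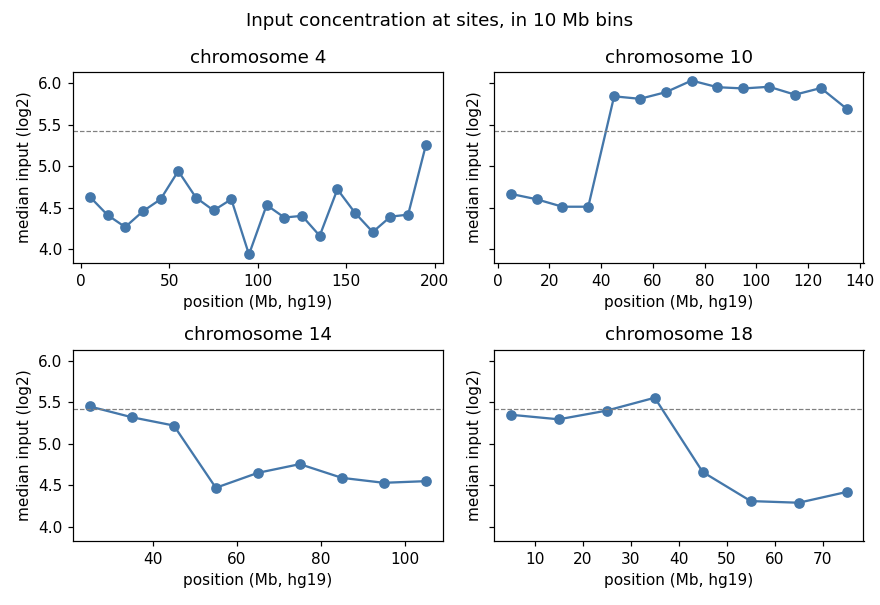
Median input concentration of sites (vertical axis, log2) in 10 Mb bins along chromosomes 4, 10, 14 and 18 (horizontal axis, Mb on hg19), with the median of all sites, 5.42, as a dashed line. Chromosome 10 had 4.60 left and 5.94 right of its step, chromosome 14 had 5.38 and 4.61, and chromosome 18 had 5.38 and 4.55, and some bins hold few sites.

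Sites over 1 kb from any listed start, and outside a protein-coding gene but within 2.5 kb of it, were counted on both sides. This comparison was chosen after seeing the data. Such a site could lie inside another coding gene: that 467 bp past the end of RPS2 lies inside NDUFB10. EGR1 and CYR61 had sites past their ends with log2 folds of 5.27 and 4.08 in the authors' deposited table. Among sites with a log2 fold of at least 2, 116 lay past an end and 23 before a start, and among weaker sites 204 and 213 (odds ratio 5.27, two-sided Fisher exact p = 1.67e-13). A site could be counted on both sides, as that of KRT17 and KRT16 was. The Fisher test does not allow for such overlap, and the number of shared sites was not determined. Sites past an end were counted from 0 bp, and those before a start only over 1 kb from it by the listed distance. With the shortest distance from 1 to 2.5 kb on both sides, 16 and 16 strong sites and 40 and 158 weaker ones remained. Over all genes of the table, coding or not, the odds ratio was 2.53.

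**Figure D5:**
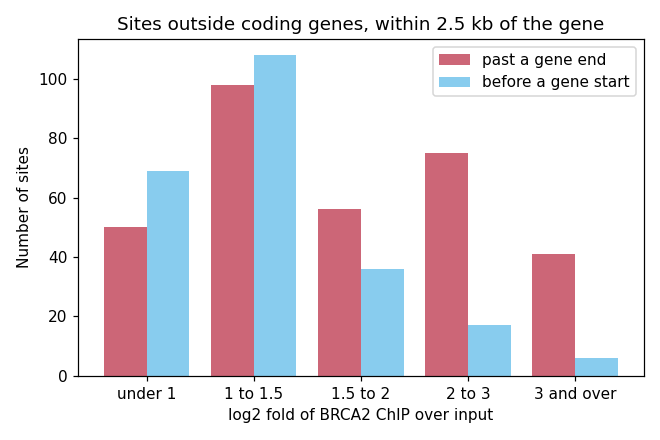
Number of sites (vertical axis) past a gene end and before a gene start, by bin of log2 fold (horizontal axis), for sites over 1 kb from any listed start and within 2.5 kb of a coding gene. Under a log2 fold of 1 there were 50 and 69 sites, and at 3 and over 41 and 6. A site can be counted on both sides.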

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

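No paired analysis was possible because the table holds group means and no value per library. For the same reason the planned runs without a replicate, with another scaling, without a low-count filter and with a replicate block were not run. Expected counts by chromosome length were not run either, since no genome of the build was at hand, and gene counts served instead. Depth per library is unknown, so no limit from depth can be given.

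Of 59 alternatives to the main values, 38 left them alike. The number above input fell to 6741 at an FDR under 0.001 and to 1200 at sites with at least 2 times the median ChIP concentration. The number below input was 0 at an FDR under 0.01, at an FDR under 0.001, with a log2 fold of at least 1 in size, and at the well covered sites. By construction each of these keeps fewer sites. At an FDR under 0.01 and at a log2 fold of at least 1, the share over a gene start was 24.2% and 24.4%, upstream 17.8% and 17.5%, downstream 10.2% and 10.3%, and at promoters 36.7% and 37.3%. Promoter windows of 3 kb and 5 kb, which are wider by construction, gave 42.05% and 48.15%. The larger fold at promoters held under the alternatives on fold, by 0.10 to 0.15, and the ChIP concentration was also higher there, by 0.08 on the log2 scale.

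Among alternatives chosen after seeing the data, sites with a log2 fold of at least 2 left 0 chromosomes above and 0 below, with a ratio of 0.895 for chromosome 4 (adjusted exact binomial p = 0.744). That cut keeps far fewer sites, so small differences between chromosomes could be missed. Sites near starts gave 6 lists below other genes in place of 3, and sites at gene ends, chosen after seeing the data, gave 7 lists above in place of 15. Near starts, the odds ratios of basal markers (0.759), fibroblast markers (0.125), immediate early genes (0.632) and fragile site genes (0.813) turned below 1. At gene ends, those of recombination genes (0.941), mitosis genes (0), pausing genes (0.683), ZNF genes (0.452), fragile site genes (0) and interferon genes (0) turned below 1, and those of keratins (1.66) and luminal markers (1.74) turned above it. At an FDR under 0.01, interferon genes (0.906) and fibroblast markers (0.845) turned below 1. Fibroblast markers, at 1.01 in the main comparison, also did so at a log2 fold of at least 1 (0.937), without chromosomes 4, 10, 13, 14, 18 and X (0.943), and as a ratio to length-matched lists (0.923). Of these, fibroblast markers near starts and ZNF genes at ends passed the test. The causes were not tested. Of the other comparisons by list, 107 kept their direction and their side of the threshold, 22 lost their call and 4 gained one. The odds ratio of lying past a gene end, chosen after seeing the data, was 5.27 and ranged from 2.53 to 5.63 over its alternatives.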

Other observations

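All tests of this part were chosen after the patterns were seen, except that of coding starts beside small RNA genes and that of shared starts, which were written before their results. Strong BRCA2 sites also lay just past the ends of genes. The site of EGR1, an immediate early transcription factor, lay 249 bp past its end, with a log2 fold of 5.27 in the authors' deposited table. CYR61 had 4.08 at 278 bp, ACTB 4.06 at 454 bp, JUNB 3.90 at 118 bp, MYC 3.76 at 556 bp and JUN 3.42 at 432 bp. A site over or within 2.5 kb past the end was held by 17 of 43 immediate early genes (39.5%, odds ratio 19.2, adjusted Fisher exact p = 3.48e-13). Ribosomal protein genes had 18 of 79 and basal markers 7 of 37 (adjusted Fisher exact p = 1.24e-09 and 0.00127). Histone, heat shock and EGF receptor genes also passed, and recombination genes, with 2 of 63, did not.

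Among sites over 1 kb from any listed start and within 2.5 kb of a coding gene, 116 with a log2 fold of at least 2 lay past an end and 23 before a start, against 204 and 213 weaker sites. Past-end sites were counted from 0 bp, and before-start sites only over 1 kb from the start by the listed distance. For this reason the ratio between strong and weak sites is given. It was 5.27 (interval 3.19 to 8.97, Fisher exact p = 1.67e-13), and 3.95 with 1 to 2.5 kb on both sides (16 and 16 strong sites). It was 3.49 with strong sites from a log2 fold of 1.5, and 2.53 over all genes of the table, with 148 and 55 strong against 504 and 474 weaker sites. A site can count on both sides, as that of KRT17 and KRT16 did, so the interval and p-values of these ratios are approximate. The pairing of sites with genes cannot be excluded as a cause of 5.27. It also lists genes that end nearby, while sites within 1 kb of a start were left out. Strong sites that lie closer to genes than weaker ones would then raise the ratio. The ratio of 3.95 has no such difference of windows, with 40 and 158 weaker sites (Fisher exact p = 0.000661), but the pairing itself was not varied. Easily sheared chromatin would give a higher input past ends, which was not seen. The median input at strong sites past ends differed from that before starts by -0.18 (permutation p = 0.303, 116 and 23 sites). With so few sites before starts, this explanation was not excluded. Non-specific pull-down of heavily transcribed DNA cannot be told apart from BRCA2 binding, since the odds ratio of 8.68 for ribosomal protein gene ends would follow from both and no control antibody was analysed here. No biological explanation was tested.

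The low count on chromosome 4 and the input level inside other chromosomes form another pattern. The input level stepped up by 1.34 between 42.7 and 43.1 Mb on chromosome 10 and by 0.615 near 79.7 Mb on chromosome 13. It changed by -0.775 near 45.6 Mb on chromosome 14 and by -0.83 near 33.7 Mb on chromosome 18, each with a permutation p of 1e-04, the smallest that the permutations can give. The same test called 13 of 23 chromosomes at an adjusted p of 0.05, with steps as small as -0.05 on chromosome 12 (adjusted permutation p = 0.0324) and 0.15 on chromosome 5 (adjusted permutation p = 0.00511), so its calls alone do not mark a large step. Whole chromosomes lost from a library would leave no step inside a chromosome, and 4 chromosomes had one over 0.5 with at least 30 sites on each side. Fewer DNA copies, with weak sites missed, may account for chromosome 4: its strong sites per gene were 0.891 of those elsewhere (interval 0.685 to 1.16) and its weak sites 0.224. For chromosome 4 alone, loss of the chromosome from 1 library cannot be told apart from a lower copy number, as its input difference of -0.91 would follow from either. Copy number was not measured here.

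Sites at small RNA genes differed by the polymerase that reads their type. Small nuclear RNA genes of the types read by Pol II had 25 sites within 1 kb of a start, with a median log2 fold of 2.00. Small RNA genes of the types read by Pol III, which include U6, 7SL, Y, vault and transfer RNA genes, RMRP and RPPH1, had 21 with a median of 1.03. RNU4ATAC had 2.43, RNU12 2.38 and RNU5A-1 2.67, against 1.42 for RN7SK, 0.98 for RMRP and 0.73 for RNU6-2. The ranges overlapped, from 0.77 to 3.67 for the Pol II types and from 0.73 to 1.56 for the Pol III types. The difference of 0.97 had a permutation p of 1e-05. Starts of coding genes nearby are argued against as its cause, since it was 0.94 (permutation p = 1e-05) without them, over 20 and 17 sites. Pseudogene symbols belonged to 11 and 9 of these sites, and without them the difference was 1.09 (permutation p = 0.00047, over 14 and 12 sites). Many of these genes have near-identical copies, between which reads can be divided, and that was not tested.

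A hypothesis that starts shared by 2 genes on opposite strands hold stronger sites predicted a higher median log2 fold there. The median log2 fold was 1.24 at 621 shared starts and 1.27 at 3559 starts of 1 gene, a difference of -0.03 (permutation p = 0.352). The predicted higher median was therefore not seen. A log2 fold of at least 4 was more frequent at shared starts, at 48 sites (7.73%) against 161 (4.52%; Fisher exact p = 0.00132), a comparison made after seeing the medians.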
